A study of Homo sapiens with 6 samples.

How the data were processed

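Total RNA from HK2 cells was labelled with biotin and hybridised to 6 Affymetrix expression arrays, 3 from cells with an shRNA against GFP and 3 from cells with an shRNA against PGC-1alpha. The authors deposited a table of log2 expression values with 53617 probe sets and 1 column per array. The submitters' processing notes name RMA (robust multi-array average, which corrects background, normalises between arrays by quantiles and summarises probes) and Affymetrix Expression Console, and their versions are not given in the sources used here. The values ran from 0.66 to 13.8, as log2 values do, and were used as deposited. RMA makes the arrays' distributions alike, so a change that moved most transcripts in 1 direction would be reduced in these values. Background correction and summarisation were not repeated from scanner files, and scan dates and batches were not analysed here.

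Groups and replicate numbers came from the sample titles. The labels call the samples biological replicates, but nothing in the labels says whether the cultures were transduced separately, so the p-values measure the spread between these samples. No 2 arrays held the same values: 13 to 119 of the 53617 probe sets were identical to the last decimal in any pair. The SD of the log2 differences over all probe sets was 0.286 to 0.348 within groups and 0.369 to 0.429 between groups. RMA values carry no counts and no detection calls, so only the number of arrays and the spread between them set the precision.

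Probe sets were named through a table that pairs them with the platform's annotation. It gave 1 gene symbol for 16098 probe sets, several for 0 and none for 37519, which are unnamed here. All 16098 gene identifiers and symbols matched the RefSeq gene table of GRCh38.p14, which was used for names and for which genes lie inside each other. The named probe sets stood for 14884 genes, of which 11916 were protein coding and 1072 microRNA genes. For 779 genes with more than 1 probe set, the probe set with the highest mean over the 6 arrays stood for the gene. Genes named here leave out several families, such as the subunits of complex I, and PPARGC1A itself.

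The groups were compared with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, no filter on dim probe sets, no replicate block), and p-values were adjusted by the Benjamini-Hochberg method over the 14884 genes, with a threshold of 0.05. Log2 differences are shPGC-1alpha minus shGFP. Gene lists were tested with limma's camera with a preset inter-gene correlation of 0.01, two-sided, and adjusted over the 37 lists with a measured member, out of 38 lists. Camera with a correlation estimated from the data and fry were alternatives. Members were counted past the threshold over all genes and adjusted over the list alone, and 556 of the 914 genes in the lists were measured. With 3 arrays against 3, an exact permutation test cannot give a p below 0.1.

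The groups, the test, the gene lists, the rule for naming genes and most alternatives were fixed before the data were examined. The text names PPARGC1A, PPARGC1B and PPRC1, the 10 genes with the largest increases and the 10 with the largest decreases among genes past the threshold whose groups did not overlap and whose higher group mean was above the background level, and in each list up to 4 members with the smallest p among those past the threshold, or 2 where none passed. Genes without a settled name, noncoding genes with serial symbols, pseudogenes and Y-linked genes were left out of the 20. Any other gene named was chosen after its values were seen. The background level was to be the 95th percentile of olfactory receptor genes, but 1 such gene was named, which gave a level of 3.04 with 877 genes below it. The 20th percentile of the named genes, 4.43, was added as a stricter guide after the data were seen.

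The procedure was tested on simulated data with the real genes' means and spread and 200 of 14884 genes changed. It called 0 genes when none were changed. It recovered 40.3% of the genes changed by 0.5 log2 units, 89.6% of those changed by 1 and 98.5% of those changed by 2, and 1.30% of its calls were of unchanged genes. A simulated list of 20 genes shifted by 0.5 was called by camera and 0 unshifted lists were. The simulated genes varied independently of each other, so this cannot test the preset correlation on lists whose members move together. With an estimated correlation the simulated list had a camera adjusted p of 0.0052, whereas 0 of the 37 real lists passed. Members that move together are not the reason in every list. The estimated correlations of metallothioneins and iron, extracellular matrix and unfolded protein response were -0.026, -0.025 and -0.046, below the preset. These lists passed with the preset and not with the estimate, and why was not tested. The alternatives tried were each array left out, the replicate number as a block, filters on dim genes, other choices of probe sets, other scalings, variance models and thresholds, array weights, and other list tests.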

Results

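Gene expression was measured in HK2 cells, an established epithelial line from the proximal tubule of the human kidney, the nephron segment that reabsorbs most of the filtered solute. The cells carried a lentiviral shRNA directed against PGC-1alpha or, as the control, an shRNA directed against GFP, which human cells do not encode. PGC-1alpha, the product of PPARGC1A, is a transcriptional coactivator known for its part in mitochondrial biogenesis and oxidative metabolism. Transduced cells were selected with puromycin, and RNA was taken on day 5, when 24 hours had passed since the end of selection. Each group held 3 arrays that the labels number as biological replicates 1 to 3, so there were 6 arrays in all. Every array gave log2 RMA values for 53617 probe sets, with array medians between 5.00 and 5.04, and the number of arrays limits the precision. Of these probe sets, 16098 were paired with a gene, which gave 14884 genes, and 37519 were not named here. PPARGC1A and its relatives PPARGC1B and PPRC1 had 0 probe sets named here, so the level of the shRNA's target was not analysed here and the labels were not checked against it.

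The arrays separated by shRNA. The first principal component held 40.3% of the variance and placed the 3 shGFP arrays between 32.0 and 41.5 and the 3 shPGC-1alpha arrays between -38.9 and -29.9. The second component held 19.6% and set shGFP replicate 1, at 42.6, apart from the other shGFP arrays, at -19.7 and -26.9. On it shPGC-1alpha replicates 1, 2 and 3 lay at 19.9, -18.2 and 2.28, so replicate 1 scored highest in both groups. Arrays of the same group correlated with each other at r = 0.988 to 0.992 over all probe sets, and arrays of different groups at r = 0.982 to 0.987.

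The comparison addressed which transcripts differ in proximal tubule cells that carry the shRNA against PGC-1alpha. Transcripts of chemokines and acute-phase proteins were among those with the largest increases. CCL20, a chemokine that attracts lymphocytes and dendritic cells, rose from 7.68 ± 0.06 (SD, n = 3) to 11.35 ± 0.08, a log2 difference of 3.67 (SE 0.07) or 12.7-fold. CXCL5, a neutrophil chemokine, rose by 3.33 (SE 0.07) or 10.1-fold, and the acute-phase protein SAA1 and complement C3 rose by 2.53 (SE 0.10) and 2.44 (SE 0.06). The largest decrease among the named genes was that of FLRT3, a transmembrane protein with leucine-rich repeats, from 9.01 ± 0.06 to 5.37 ± 0.37, a log2 difference of -3.64 (SE 0.17) or a 12.5-fold lower level. The DNA replication genes MCM6 and GINS2 were also lower, at -0.92 (SE 0.07) and -0.78 (SE 0.07).

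Among genes with settled names, the others of the 10 with the largest increases were VNN2, at 2.92 (SE 0.12), the kinase PIM2, at 2.48 (SE 0.06), the R-spondin receptor LGR4, at 2.40 (SE 0.08), the kinase MAP3K8, at 2.39 (SE 0.17), the ectonucleotidase ENPP3, at 2.21 (SE 0.07), and the ubiquitin ligase RNF144B, at 2.13 (SE 0.08). The limma adjusted p of these 10 genes lay between 2.3e-06 for CCL20 and 0.00019 for MAP3K8. On the same terms, the largest decreases after FLRT3 were those of the kinase CDKL2, at -2.47 (SE 0.09), PSG8, at -2.21 (SE 0.30), the guanine nucleotide exchange factor VAV3, at -2.04 (SE 0.13), and the collagenase MMP13, at -1.95 (SE 0.09). They were followed by the transcription factor NFIB, at -1.93 (SE 0.07), SEC14L6 and ZFHX4, both at -1.79 (SE 0.11), CRISPLD2, at -1.74 (SE 0.07), and the long noncoding RNA UCA1, at -1.73 (SE 0.07). The limma adjusted p of these 10 genes lay between 1.7e-05 for CDKL2 and 0.0022 for PSG8. PSG8 belongs to a family of near-identical genes whose probes can share transcripts, so its value is uncertain. The mean of VNN2 in the control group, 4.24, and the means of PSG8, VAV3 and MMP13 in the shPGC-1alpha group, 3.95, 3.58 and 3.86, lay below 4.43, the 20th percentile of the named genes.

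**Figure D1:**
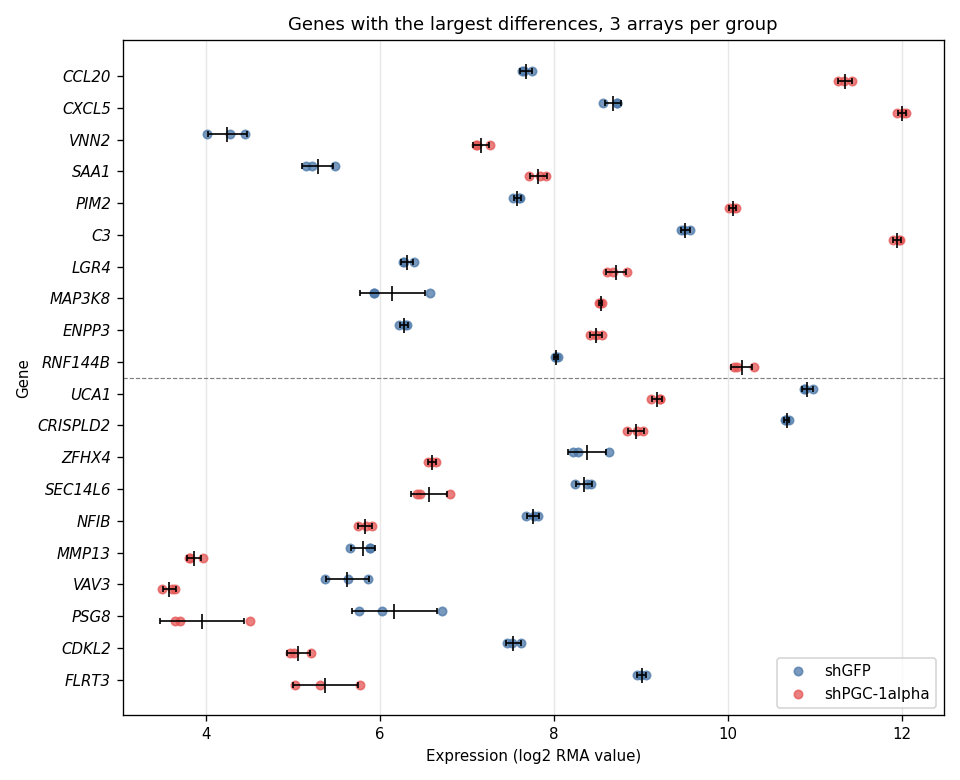
Expression of the 10 genes with the largest increases (upper part) and the 10 with the largest decreases (lower part) in log2 RMA units on the horizontal axis, with genes on the vertical axis. Each point is an array (blue, shGFP; red, shPGC-1alpha; 3 arrays per group), vertical ticks are group means and bars are SDs; CCL20 went from 7.68 to 11.35 and FLRT3 from 9.01 to 5.37, and the groups did not overlap in any of the 20 genes.

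Over all 14884 genes, 3243 (21.8%) passed an adjusted p of 0.05 in limma, of which 1426 were higher and 1817 lower with the shRNA against PGC-1alpha. Most of these differences were small. The median log2 difference was 0.43 among the genes that rose and -0.45 among those that fell, and 116 genes rose and 102 fell by at least 1 log2 unit. The arrays of the groups did not overlap for 5757 genes (38.7%), against 10% by chance, and the median SE of a log2 difference was 0.088.

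Among the gene lists, that of NF-kB and cytokine genes had the lowest p. Of its 23 measured members, 16 rose and 0 fell (18 rose adjusted over the list alone), with a median log2 difference of 0.77. The members that rose included the neutrophil chemokines CXCL8, at 1.83, and CXCL2, at 1.72, the macrophage growth factor CSF1, at 1.81, the adhesion molecule ICAM1, at 1.07, and the NF-kB subunits NFKB1, at 0.80, and NFKB2, at 0.77. TNF, at 0.01, and PTGS2, at 0.21, did not pass. The list's adjusted p in camera was 1.8e-15, and its adjusted p = 0.10 with an estimated correlation. Interferon response genes went both ways: of 27 measured, 4 rose and 4 fell (4 and 5 adjusted over the list alone), with a median of 0.02 and a camera adjusted p of 0.937. IFI44 rose by 1.12, SAMD9L by 0.78 and the transcription factor IRF1 by 0.54, whereas IFIT1 fell by 1.27 to a mean of 3.83, and RIGI, a sensor of viral RNA, fell by 0.58. Among genes of microRNA processing and RNA interference, EIF2AK2, the kinase PKR that responds to double-stranded RNA, fell by 0.42 and TNRC6A rose by 0.31, 1 gene each way of 7 measured (likewise adjusted over the list alone; camera adjusted p 0.946). The call of TNRC6A was lost without each single array other than shGFP replicate 1, and its adjusted p reached 0.0979 over the alternatives. Of 13 apoptosis regulators 3 rose and 3 fell (likewise adjusted over the list alone; camera adjusted p 0.286). The pro-apoptotic genes PMAIP1 and BID rose by 1.02 and 0.61, the pro-apoptotic BCL2L11 fell by 0.41 and the anti-apoptotic BCL2 fell by 0.32.

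Several lists of cellular stress were also higher. Of 17 measured hypoxia targets, 11 rose and 2 fell (13 and 2 adjusted over the list alone), with a median of 0.50. The peptide hormone gene ADM rose by 1.08, the collagen-crosslinking enzyme LOX by 1.02, STC2 by 0.88 and the oxygen sensor EGLN1 by 0.66. The hypoxia list had a camera adjusted p of 1.5e-06 and an adjusted p = 0.143 with an estimated correlation. Of 20 genes of the integrated stress response, 12 rose and 1 fell (13 and 1 adjusted over the list alone), with a median of 0.32. They included the stress cytokine GDF15, at 0.82, the serine synthesis enzyme PSAT1, at 0.67, and DDIT4, an inhibitor of mTORC1 signalling, at 0.55. This list had a camera adjusted p of 1.9e-05 and an adjusted p = 0.171 with an estimated correlation. Of 11 genes of the unfolded protein response, 6 rose and 1 fell (8 and 2 adjusted over the list alone), with a median of 0.24. The endoplasmic reticulum stress sensor ERN1 rose by 1.31, HYOU1 by 0.50, the transcription factor XBP1 by 0.46 and MANF by 0.40. Camera gave this list an adjusted p of 0.0025, and an adjusted p = 0.159 with an estimated correlation. In the list of metallothioneins and iron genes, 6 of 10 measured members rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.81. All 6 were metallothioneins, small metal-binding proteins, and included MT1M, at 1.43, MT1X, at 1.24, MT1F, at 1.23, and MT1E, at 1.07. Their near-identical sequences can share probes, so the single values are uncertain and the 6 rises may not be separate signals. The count, the median and the camera p of the list carry the same uncertainty. The list's adjusted p in camera was 8.6e-05, with an adjusted p = 0.143 with an estimated correlation. NRF2 targets did not pass as a list in camera (2 of 8 rose and 1 fell, 3 and 1 adjusted over the list alone; camera adjusted p 0.358; higher in fry, adjusted p 0.0090), although HMOX1, which degrades heme, rose by 1.12 and glutathione reductase GSR fell by 0.38. Antioxidant enzymes did not pass either (2 of 15 rose and 3 fell, 4 and 3 adjusted over the list alone; camera adjusted p 0.622). PRDX2 and the mitochondrial PRDX3 fell by 0.63 and 0.41 and GPX8 rose by 0.49. Of 10 heat shock genes 1 rose, the co-chaperone BAG3 at 0.38 (1 adjusted over the list alone; camera adjusted p 0.522). Some of these small counts changed with 1 array left out. The count over all genes fell then too, from 3243 to between 2328 and 2578. The count of NRF2 targets that rose was 1 without shGFP replicate 1 or 2 or shPGC-1alpha replicate 1 or 2, the count of hypoxia targets that fell was 1 without each array other than shPGC-1alpha replicate 1, and the unfolded protein response gene that fell, ATF6, was lost without any of the 6 arrays.

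Genes of lipid synthesis moved in different directions. Of 17 measured cholesterol biosynthesis genes, 8 rose and 1 fell (11 and 1 adjusted over the list alone), with a median of 0.34. INSIG1, a sterol-regulated protein that restrains the pathway, rose by 1.13, and the enzymes HMGCS1, SQLE and MSMO1 rose by 0.73, 0.59 and 0.54. The list had a camera adjusted p of 9.3e-05 and an adjusted p = 0.191 with an estimated correlation. Of 15 fatty acid synthesis genes, 1 rose and 5 fell, the same counts adjusted over the list alone, and the list did not pass in camera (adjusted p 0.522). The desaturases SCD and FADS1 fell by 0.44 and 0.36. Fatty acid oxidation genes also went both ways, with 3 higher and 5 lower of 13 measured, the same counts adjusted over the list alone, and a camera adjusted p of 0.999. The acyl-CoA synthetase ACSL1 and CPT1A, which starts fatty acid entry into mitochondria, rose by 1.45 and 0.71, while CPT2, the next enzyme of that route, and ETFDH fell by 0.47 and 0.42. Of 13 genes of NAD biosynthesis, 3 rose and 1 fell, the same counts adjusted over the list alone, and the list did not pass in camera (adjusted p 0.522). NAMPT, the rate-limiting enzyme of the salvage of nicotinamide, rose by 0.81, PNP by 0.58 and KYNU by 0.41. Among 9 glycolysis genes, the hexokinase gene HK2 rose by 0.44, the isomerase TPI1 rose by 0.57 and LDHB fell by 0.30 (4 higher and 1 lower adjusted over the list alone; camera adjusted p 0.259). Of 3 measured gluconeogenesis genes 0 passed (1 rose adjusted over the list alone; camera adjusted p 0.459), with PC and PCK1 both at 0.21. The single genes counted as lower in the cholesterol, glycolysis and NAD lists, EBP, LDHB and NAPRT, were each lost without shGFP replicate 1 and without shGFP replicate 3. EBP was also lost without shPGC-1alpha replicate 2 or 3, LDHB without shGFP replicate 2 or shPGC-1alpha replicate 1 or 3, and NAPRT without shGFP replicate 2 or shPGC-1alpha replicate 1 or 2. ELOVL6, the fatty acid synthesis gene that rose, was lost without each array other than shPGC-1alpha replicate 3, and the count of that list's genes that fell was 3 without shGFP replicate 1 and 2 without shGFP replicate 2 or 3 or shPGC-1alpha replicate 2 or 3.

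Mitochondrial genes, which include well-known targets of PGC-1alpha, did not pass as lists in camera. The fry test of direction, which asks whether a list's genes move 1 way on balance and does not compare them with other genes, called complexes II and III (adjusted p 0.0085) and the tricarboxylic acid cycle (adjusted p 0.044) lower. Of the 5 measured subunits of respiratory complexes II and III, CYC1, the cytochrome c1 of complex III, fell by 0.51 (1 lower adjusted over the list alone; camera adjusted p 0.358). Of 14 complex IV genes, COX7A2L rose by 0.28 (1 higher adjusted over the list alone; camera adjusted p 0.522), a call lost without shGFP replicate 2 (adjusted p 0.0630). The 2 measured complex V genes, ATP5MJ at 0.08 and ATP5IF1 at -0.05, did not pass (0 adjusted over the list alone; camera adjusted p 0.893), and 0 of 37 complex I genes were named here. Of 10 genes of the tricarboxylic acid cycle 0 passed, likewise adjusted over the list alone (camera adjusted p 0.522), with DLAT, a subunit of pyruvate dehydrogenase, at -0.22. Of 5 genes of mitochondrial DNA maintenance and transcription 0 passed (1 rose and 2 fell adjusted over the list alone; camera adjusted p 0.522), with the helicase TWNK at 0.20 and the RNA polymerase POLRMT at -0.21. Mitochondrial ribosomal proteins were the largest of these lists, with 4 higher and 6 lower of 58 measured, the same counts adjusted over the list alone, a median of -0.04 and a camera adjusted p of 0.522. MRPL11 fell by 1.42 (SE 0.11), far more than MRPL15, at -0.45, or MRPL27, at -0.33, and MRPL33 rose by 0.48. Of 24 import genes 5 rose and 2 fell (6 and 2 adjusted over the list alone; camera adjusted p 0.358), among them the inner membrane translocase subunit TIMM17B, which fell by 0.42, and TOMM34, which rose by 0.31. Of 13 genes of mitochondrial dynamics and mitophagy 2 rose and 1 fell (4 and 1 adjusted over the list alone; camera adjusted p 0.719), with the prohibitin PHB2 at -0.79 and the mitophagy receptor BNIP3 at 0.33. Among 14 measured partners of PGC-1alpha 1 rose and 1 fell, the same adjusted over the list alone (camera adjusted p 0.815). SIRT1, the deacetylase that acts on PGC-1alpha, fell by 0.68, and the nuclear receptor PPARD rose by 0.43. Several of these counts changed with 1 array left out. The count over all genes also fell then, from 3243 to between 2328 and 2578, whichever array was left out. Without shGFP replicate 2, 1 mitochondrial ribosomal gene rose and 3 fell, 1 import gene and 1 gene of mitochondrial dynamics rose, and 2 partners of PGC-1alpha fell. Without shGFP replicate 3, 1 mitochondrial ribosomal gene rose, and without shPGC-1alpha replicate 1 or 2 it was 2. The count of import genes that rose was 1 to 3 with any 1 of the 6 arrays left out, and the count of those that fell was 1 without each array other than shGFP replicate 1.

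Of 41 measured cell cycle genes, 5 rose and 15 fell (6 and 18 adjusted over the list alone), with a median of -0.11. Among the largest decreases were the helicase subunits MCM6 and MCM5 at -0.92 and -0.81, cyclin E1 (CCNE1) at -0.92 and GINS2 at -0.78. Mitotic genes were among those that did not pass, such as MKI67, at 0.00, and CCNB1, at -0.08, and the mitotic BIRC5 rose by 0.40. The list's adjusted p in camera was 0.026, and its adjusted p = 0.726 with an estimated correlation. The call was lost without shGFP replicate 2 (adjusted p 0.0566), without shPGC-1alpha replicate 3 (0.0814), on ranks (0.0601) and among genes above the 20th percentile (0.0612), and the count of genes that rose was 3 to 4 with any 1 array left out and 3 without each array other than shPGC-1alpha replicate 3. The p53 targets did not pass as a list in camera or in fry, with 3 higher and 3 lower of 12 measured (4 and 3 adjusted over the list alone; camera adjusted p 0.822). PLK3 and GDF15 rose by 0.91 and 0.82, and TP53I3 and CCNG1 fell by 0.43 and 0.42.

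In the list of extracellular matrix genes and TGF-beta targets, 6 of 15 measured members rose and 0 fell (7 and 0 adjusted over the list alone), with a median of 0.16. The matrix protein gene TNC rose by 1.36, LOX by 1.02, the collagenase MMP1 by 0.84 and SMAD7, an inhibitor of TGF-beta signalling, by 0.45. Its camera adjusted p was 0.00093, and its adjusted p = 0.143 with an estimated correlation. Of 19 genes of epithelial and mesenchymal state, 2 rose and 7 fell (3 and 9 adjusted over the list alone), with a median of -0.25 and a camera adjusted p of 0.259. The keratin KRT19 and the epithelial adhesion molecule EPCAM fell by 1.42 and 0.73, while the tight junction gene CLDN1 and ZEB2, a repressor of epithelial genes, rose by 1.33 and 1.34. The mesenchymal marker VIM, at 0.09, did not pass. Of 23 lysosome and autophagy genes, 9 rose and 2 fell (11 and 2 adjusted over the list alone), with a median of 0.15. The protease CTSB rose by 0.59, RRAGD by 0.67 and the autophagy receptor SQSTM1 by 0.50, and the transcription factor MITF fell by 1.22. The lysosome list had a camera adjusted p of 0.0027 and an adjusted p = 0.234 with an estimated correlation. Of 30 cytosolic ribosomal protein genes 0 passed in limma, and 0 adjusted over the list alone (camera adjusted p 0.522), with RPL11 at -0.18 and RPL19 at 0.18. At an unadjusted p of 0.05, 4969 of all genes passed.

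Markers of the proximal tubule and of other cell types did not pass as lists in camera, while fry called proximal tubule markers lower (adjusted p 0.018) and fibroblast and pericyte markers higher (0.0047). Of 12 measured proximal tubule markers 2 rose and 4 fell (2 and 5 adjusted over the list alone; camera adjusted p 0.522). The brush border peptidase MME fell by 0.61, HAVCR1, a marker of tubular injury, fell by 0.36, the adhesion molecule VCAM1 rose by 0.57 and GATM, which makes the precursor of creatine, rose by 0.55. Of 10 markers of other nephron segments, SYNPO, an actin-binding protein of podocytes, fell by 0.93 (1 higher and 2 lower adjusted over the list alone; camera adjusted p 0.719). Fibroblast and pericyte markers went both ways, with 3 higher and 2 lower of 7, the same adjusted over the list alone (camera adjusted p 0.458). The proteoglycan genes LUM and DCN rose by 0.76 and 0.83, DCN from a mean of 3.80 to 4.63, and MCAM and NOTCH3 fell by 0.49 and 0.35. Of 11 endothelial markers ESAM rose by 0.27 (0 adjusted over the list alone; camera adjusted p 0.433), and of 10 immune cell markers CD68 rose by 0.34 and CSF1R and TYROBP fell by 0.48 and 0.28 (the same counts adjusted over the list alone; camera adjusted p 0.946). The calls of ESAM and TYROBP did not hold: that of ESAM was lost without each array other than shGFP replicate 3, and that of TYROBP without each array other than shPGC-1alpha replicate 2. The count of proximal tubule markers that fell was 2 to 3 with 1 array left out, with 2 without shGFP replicate 1 or shPGC-1alpha replicate 2 or 3, and without shGFP replicate 2 there was 1 marker of other nephron segments that rose.

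**Figure D2:**
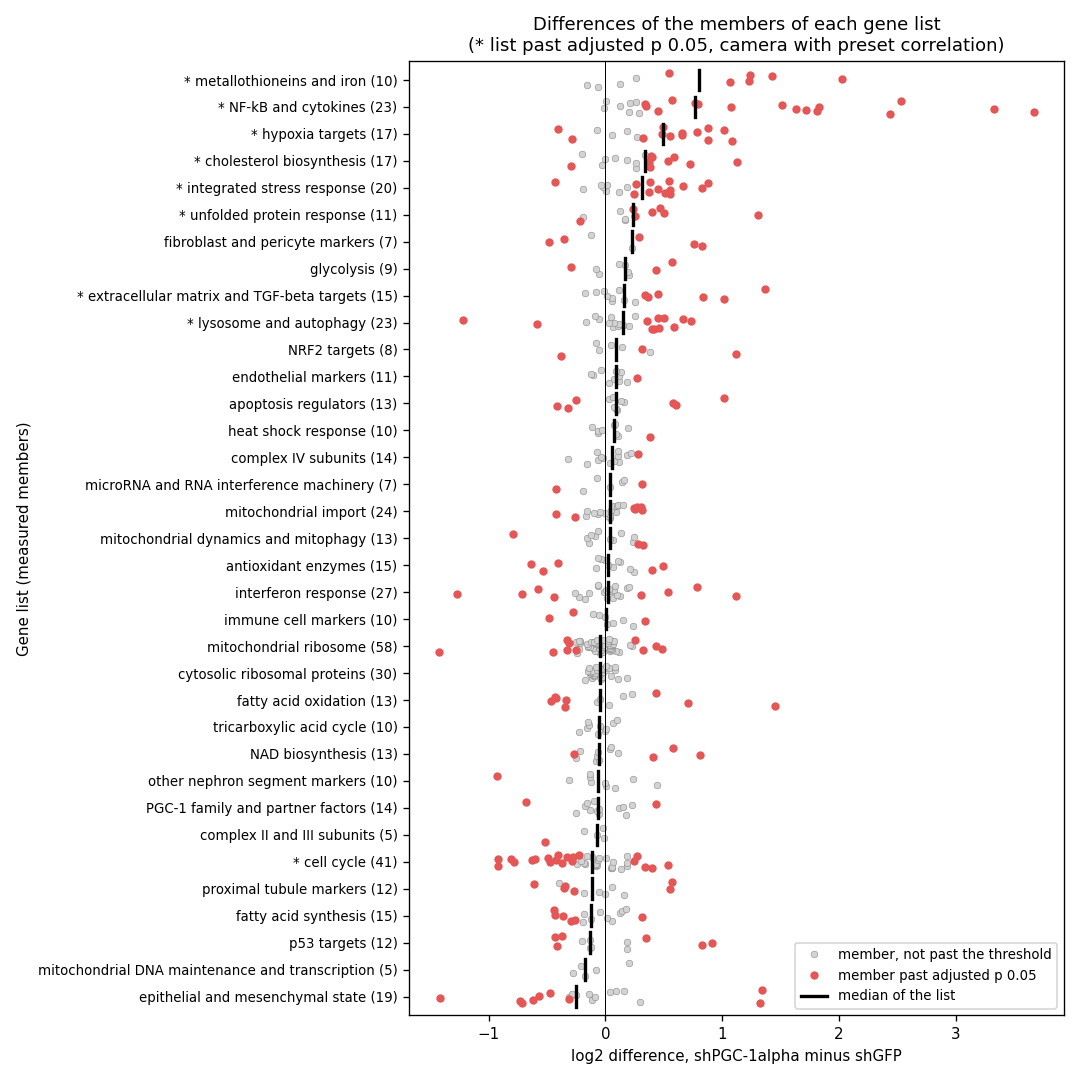
Log2 differences, shPGC-1alpha minus shGFP, of the measured members of gene lists are on the horizontal axis. The lists are on the vertical axis, ordered by median, with the number of measured members in parentheses. Lists with fewer than 5 measured members, namely gluconeogenesis (3), complex V (2) and complex I (0), are not drawn. Red points passed an adjusted p of 0.05 and grey points did not, black bars are list medians, and asterisks mark the 9 lists past an adjusted p of 0.05 in camera with the preset correlation; the medians ran from 0.81 for metallothioneins and iron to -0.25 for epithelial and mesenchymal state.

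Of the 37 lists with measured members, 9 passed in camera with the preset correlation, 8 higher and 1 lower, and 0 passed with an estimated correlation, where the lowest adjusted p was 0.10. The fry test of direction called 14 lists higher and 6 lower, and its mixed test called 36. The 14 were the 8 that camera called higher, with NAD biosynthesis (adjusted p 0.0023), glycolysis (0.0047), fibroblast and pericyte markers (0.0047), gluconeogenesis (0.0075), apoptosis regulators (0.0075) and NRF2 targets (0.0090). The 6 were complexes II and III (0.0085), tricarboxylic acid cycle (0.044), fatty acid synthesis (0.021), cell cycle (0.0047), epithelial and mesenchymal state (0.044) and proximal tubule markers (0.018). The median and the mean differed in sign in 8 lists, namely fatty acid oxidation, mitochondrial dynamics, antioxidant enzymes, NAD biosynthesis, p53 targets, interferon response, immune cell markers and RNA interference. In 3 of them, fatty acid oxidation, NAD biosynthesis and p53 targets, the median was below 0 and the direction in camera was higher.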

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

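The test of every probe set by itself was planned, and setting apart the probe sets that are not named here was chosen after their number was seen. A signal lay in data that the comparison of named genes does not use. Of the 37519 probe sets not paired with a gene here, 1763 (4.70%) passed an adjusted p of 0.05 when all 53617 probe sets were tested in limma, 821 higher and 942 lower with the shRNA against PGC-1alpha. In the same test 1800 of the 16098 named probe sets (11.2%) passed. The log2 differences of the unnamed probe sets ran from -3.16 to 3.98, the upper end above the 3.67 of CCL20, and 164 of them were higher and 139 lower by at least 1 log2 unit.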

How the results depend on the processing

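The filter at the 20th percentile, the test of named probe sets by themselves and the counts per list and for the pooled mitochondrial lists with 1 array left out were chosen after the data were seen, and the other alternatives were planned. Without 1 array at a time, 1011 to 1170 genes were higher and 1301 to 1502 lower, against 1426 and 1817 with all arrays. Under the filters, scalings, variance models, probe set choices and array weights the counts stayed within 1.5 times of these, at 1200 to 1763 higher and 1395 to 2207 lower. With every probe set tested by itself the 1628 higher and 1935 lower include unnamed ones. There 1800 named probe sets passed, against 1465 higher and 1824 lower when named probe sets were tested alone. More probe sets enter both that adjustment and the variance estimate that limma shares across probe sets, and these effects were not separated. Stricter thresholds moved the counts of genes by construction, to 758 higher and 942 lower at an adjusted p of 0.01, and to 116 higher and 102 lower at a log2 size of at least 1. Across the settings in which the genes were compared one by one, 0 genes called both there and in the main comparison changed direction. The direction of genes not called in both was not counted. The scalings kept the median of all genes within 0.1 of 0, at -0.003 and -0.006. The count of lists that were higher was 8 in each fit without 1 array. It fell to 0 with an estimated correlation and was 14 in the fry test of direction. The count of lists that were lower was 0 to 1 without 1 array, 0 with an estimated correlation, 0 on ranks, 0 above the 20th percentile and 6 in fry. The list lost in these was that of cell cycle genes, and the cause was not tested. Of the 118 named genes past the threshold, 0 to 12 were lost in any of 13 settings, 12 without shGFP replicate 2, 0 reversed, and the 20 genes with the largest differences passed in all 13. TOMM40 had an adjusted p of 0.999 with the mean of its probe sets, which disagree. With the replicate number as a block, 1221 genes were higher and 1552 lower, 2615 of the 2773 shared with the fit without the block, and the lists stayed at 8 and 1. Deviations of same-numbered samples correlated at 0.117, 0.0874 and 0.0230, not all above 0.1, so the numbers were not taken to pair the samples, although 5 of 6 samples correlated best with their own number. The alternatives planned for PPARGC1A were not run, since it is not named here. Signal near background limits folds of dim genes: 2977 genes lay below the 20th percentile.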

Other observations

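The tests in this part were chosen after the results were seen, except the count of gene lists over other splits of the arrays and the fry test. The genes and microRNA precursors named here were likewise chosen after their values were seen. Outside the lists, 5 further genes with large increases were picked by eye, with no test of them as a group. ZC3H12A, an RNase that degrades cytokine transcripts, rose by 2.05, ALOX5AP, which serves leukotriene synthesis, by 1.94, the PD-1 ligand gene PDCD1LG2 by 1.77, the protease CTSS by 1.72 and the receptor IL6R by 1.68, all past an adjusted p of 0.05 in limma.

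The array also holds probe sets for microRNA precursors, of which 466 were above the 20th percentile of the named genes. MIR205, a microRNA gene typical of epithelial cells, fell by 2.62 (SE 0.07), a 6.16-fold lower level. MIR146A, a microRNA known to restrain NF-kB signalling, rose by 1.38 (SE 0.09) and MIR3142 by 1.61 (SE 0.13) from a shGFP mean of 3.72, below the 20th percentile of 4.43, so the size of its rise is not exact. MIR221 and MIR222, which come from 1 cluster, rose by 0.73 (SE 0.08) and 0.59 (SE 0.13). These probe sets read total RNA, so their values are of the region of the precursor and not of the mature microRNA.

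A hypothesis is that many of these probe sets follow the transcript of the gene that holds the microRNA. Over 186 pairs of a microRNA and the single named protein-coding gene around it, the log2 differences correlated across genes, which are not independent replicates. Spearman's rho was 0.275 and Pearson's r 0.336 (permutation p 2.0e-04 for rho, 100000 permutations). Pairs were set by position without regard to strand, so a microRNA may lie on the strand opposite the gene. With 1 mean value for each of the 169 holding genes, rho was 0.260 (permutation p 7.3e-04). Of the 10 pairs in which both passed, 7 went the same way, from 5 holding genes, such as MIR25 and MIR106B, at -0.52 and -0.38, inside MCM7, at -0.49, and MIR3189, at 1.26, inside GDF15, at 0.82. MIR93, also inside MCM7, was at -0.12 and did not pass. The other 3 pairs went opposite ways: MIR3198-1, at -1.04, inside BID, at 0.61, MIR330, at -0.34, inside EML2, at 0.28, and MIR3135A, at -0.40, inside KAT2B, at 0.70. The correlation is consistent with the hypothesis for part of these probe sets and leaves most of their spread unexplained.

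With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. The real split gave 3243 genes past the threshold and was the only 1 of the 10 with as many, and the highest of the others gave 0. For the gene lists in camera with the preset correlation, it was again the only 1 of the 10 with as many, with 9 lists, and the highest of the others gave 4. Every other split mixed arrays of both groups, so any difference between them widened its spread and low counts were partly set in advance.

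The rise of NF-kB and cytokine genes (median 0.77) was weighed against 3 technical explanations. Scaling between arrays would move genes of the same mean level alike. The 2031 genes nearest in level to the members (100 for each) had a median of -0.0159 with an SD between genes of 0.32. RMA had already made the arrays' distributions alike, so a median near 0 was largely set in advance and cannot decide this. It shows only that genes of this level did not shift together in the values used. Chemokine and serum amyloid probe sets that read each other's transcripts were argued against, as the whole cause, by the 15 remaining members. Of these 10 rose and 0 fell, with a median of 0.45 (camera adjusted p 2.0e-09, and 0.118 with an estimated correlation, where the whole list had 0.10). Whether the chemokine and serum amyloid probe sets read each other's transcripts was not tested. An interferon response to double-stranded RNA from the vector would raise interferon genes alike, and their median was 0.0205 with an SD between members of 0.45. Both groups carried an shRNA, so a response that they shared would cancel in the difference. The median therefore bears only on a response that differed between the groups, and cannot show whether a shared one was present. A lower level of PGC-1alpha and an effect of this shRNA on other transcripts both stay open and untested, since PPARGC1A is not named here.

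That the mitochondrial lists did not pass in camera could reflect low power or missing members. Over the 118 measured of 204 genes in 8 lists (complexes I to V, tricarboxylic acid cycle, mitochondrial DNA, ribosome and import), 10 rose and 9 fell, and the mean over these genes relative to all genes differed by -0.01 (95% interval -0.08 to 0.05; two-sided exact permutation p 0.7; camera adjusted p 0.848). The counts were 6 and 7 without shGFP replicate 1, 2 and 5 without shGFP replicate 2, 4 and 7 without shGFP replicate 3, 5 and 8 without shPGC-1alpha replicate 1 or 2, and 8 and 6 without shPGC-1alpha replicate 3, where the difference was 0.01. The lower bound of -0.0794 (-0.11 to -0.06 with 1 array left out) argues against a fall of 0.25 in the mean of the measured genes hidden by the spread between arrays, and not against a fall in a single list, of which fry called complexes II and III (adjusted p 0.0085) and the tricarboxylic acid cycle (0.044) lower. Of the 118 measured genes, 58 were of the mitochondrial ribosome and 24 of import. Complexes II and III gave 5, complex IV 14 and complex V 2, so the mean says little about the respiratory chain. As 57.8% of the members were measured and complex I was not, whether the other members fell cannot be told apart from no change, and no biological explanation was tested.

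The 8 MCM and GINS members of the cell cycle list, set apart after their falls were seen, all fell, with a median of -0.62, whereas its 22 mitotic members had a median of 0.0503 (SD between members 0.18), 4 higher and 1 lower. The other 11 members, with 1 higher and 6 lower, had a median of -0.24 and an SD of 0.34. Of all 10 measured genes with MCM symbols, 8 fell, with a median of -0.45 (camera adjusted p 0.0021 over 323 symbol families; adjusted p = 0.997 with an estimated correlation). Fewer dividing cells would lower the mitotic members too, and their median of 0.0503 argues against fewer dividing cells as the whole cause. The parts were chosen after the values were seen, so the gap between their medians was partly set in advance and is no further argument. A shift in the share of cells entering S phase may be involved and was not tested.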
